A study of Mus musculus with 2 samples.

How the data were processed

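Total RNA from 2 cultures of CT26, a mouse colon carcinoma cell line, was measured on Illumina mouse whole-genome bead arrays, per the labels. One culture carried the empty hairpin vector pLKO.1 (control) and the other the same vector with a short hairpin RNA against CDK8 (knockdown). RNA was isolated with a Qiagen RNeasy kit and amplified to biotin-labelled cRNA with an Ambion kit, per the labels' protocols. Each group had 1 array, so nothing estimated the spread between replicate cultures. No p-value was computed, and the number of arrays limits the precision of every value.

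The deposited non-normalized table holds 1 raw intensity per probe and array for 45281 probes, exported with GSGX 1.9.0 without normalization and without background subtraction, per the file headers. It carries neither detection p-values nor bead errors. The second deposited table holds the authors' processed intensity values. No source used here states how they were made; the values themselves are linear, 29.8% of them lie below 0 on each array, and the sorted columns of both arrays differ by at most 0.1, which is what background subtraction and quantile normalization give. The medians of both columns are 3.4. Centring and any further scaling of that table stay unknown, so it served only as an alternative. Gene differences from it and from the main processing had a Pearson r of 0.997 across genes detected on both arrays, and those of all probes, detected or not, of 0.888; neither genes nor probes are independent replicates.

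Total raw intensity was 1.40e+07 on the control array and 1.46e+07 on the knockdown array. The planned background correction needed detection p-values, and the background was therefore taken from the raw intensities. On each array the peak of the dim probes marked the background (88.6 on the control and 88.0 on the knockdown array), and the values below the peak, mirrored to the upper side, gave its SD (2.56 and 2.50). A probe counted as detected above the upper 1% of this mirrored background, which was 94.5 on the control array and 93.7 on the knockdown array. This called 46.1% and 47.3% of the probes detected. True negative controls often have a longer upper tail than a mirrored one, so this floor may be lenient. It counted 147 genes of the olfactory receptor family as detected on at least 1 array, which points the same way. Intensities were corrected with the normexp function of limma 3.58.1 in R 4.3.3 at these background values, an offset of 16 was added, and the arrays were quantile normalized and put on the log2 scale. The offset draws differences of dim probes towards 0.

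A gene's value was the mean over its probes detected on at least 1 array. Of the probes, 31508 carried an Entrez gene number, and 29586 of these numbers were found in a RefSeq gene table of assembly GRCm38.p6, through which 5839 older symbols were updated; otherwise the symbol of the deposited table was kept. No source used here names a genome build for the probes, so the assembly served only for gene names and for which genes lie on the same chromosome or next to each other. Differences are knockdown minus control on the log2 scale. The SD between probes of 1 gene, pooled over 4448 genes with 2 or more detected probes, was 0.21. It describes probes on the same arrays and not cultures. For a gene detected on 1 array only, the detected value was set against the higher of its own value and the lowest detected value on the other array and is given as a bound. Where other probes of the gene were detected on both arrays, a probe detected on 1 array only entered the gene's mean at its measured value, so the means of genes such as Adam8, Ccn4, Cdc6, Elf3, Mmp13, Mmp14, Sesn1 and Timp3 hold a value not above background.

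Before the data were examined, 32 gene lists were fixed: 24 for pathways, complexes and cell states, 4 controls and 4 of markers of other cell types. The median difference of each list with at least 3 detected genes was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Such a percentile describes these arrays, since genes of a list are not independent and no culture was repeated. The rule for named genes was fixed at the same time. It took Cdk8 and the detected members of the Mediator kinase module, metalloproteinase, metalloproteinase inhibitor and plasminogen lists, the 12 highest and 12 lowest genes detected on both arrays whose symbol is not a clone or locus identifier, the 5 largest bounds in each direction, and up to 4 members with the largest differences in each other pathway list. Further genes are named as examples, chosen after their values were seen. Some genes that the rule selects are not reported here.

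The processing was tested on simulated arrays built from the measured intensities, with 100 genes changed 4-fold and 100 changed 2-fold. Of each set, 86 were detected on both arrays. The median estimate was 1.70 for the 4-fold genes and 0.81 for the 2-fold genes on the log2 scale, and at a level of 7 or more it was 1.90 and 0.98. Unchanged genes received noise of the size of the SD between probes and of the background, and no spread between cultures. Among 12166 of them, 0 reached 2-fold, which does not show how many genes would differ 2-fold between replicate cultures. Of 100 unchanged lists of 30 genes, 3 fell outside the central 95%. When 0.3 was added to the finished gene differences of each list, all 100 lists were found. That shift did not pass through the processing, so it tested the list percentile only. Alternatives fixed in advance were no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed values, a 5% detection limit, no detection limit, the brightest probe of a gene, lists restricted to genes on both arrays, unmatched random lists, and counts over genes on at least 1 array. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used for the gene-level steps. No probe sequences were used here.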

Results

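The study compared the transcriptome of CT26 mouse colon carcinoma cells carrying a short hairpin RNA against CDK8 with that of cells carrying the empty vector. CDK8 is a cyclin-dependent kinase of the Mediator complex, which links transcription factors to RNA polymerase II. The series title places the question in liver metastasis of colon cancer and in matrix metalloproteinases, the secreted and membrane-bound proteases that cut extracellular matrix. The control and the knockdown group each had 1 array. The differences below therefore have no replicate check, and "higher" and "lower" refer to these arrays.

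Cdk8 itself was lower on the knockdown array. Its log2 value was 9.88 in the control and 7.89 in the knockdown, a difference of -1.99 or 3.96-fold. This came from 1 of the 3 Cdk8 probes, with raw intensities of 992.5 and 317.9, both well above the background peaks of 88.6 and 88.0. The other Cdk8 probes were at background on both arrays. The direction is that of the label. With undetected probes averaged in, the difference was -0.69.

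Across the array, 13613 genes were detected on both arrays, 1247 on the control array only and 1606 on the knockdown array only. The values of both arrays had a Pearson r of 0.991 across genes, which are not independent replicates, and 99.0% of genes differed by less than 2-fold. At least 2-fold higher in the knockdown were 67 genes, and 75 genes were at least 2-fold lower. At 1.5-fold, 283 genes were higher and 302 lower. Of the 2-fold genes, 35 had at least 2 detected probes, and in all 35 each probe had the same direction. Of all 2-fold genes, 40 had a mean log2 level under 6, close to background. These counts depend on how dim probes are handled: with an offset of 50, 33 genes were higher and 34 lower.

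**Figure D1:**
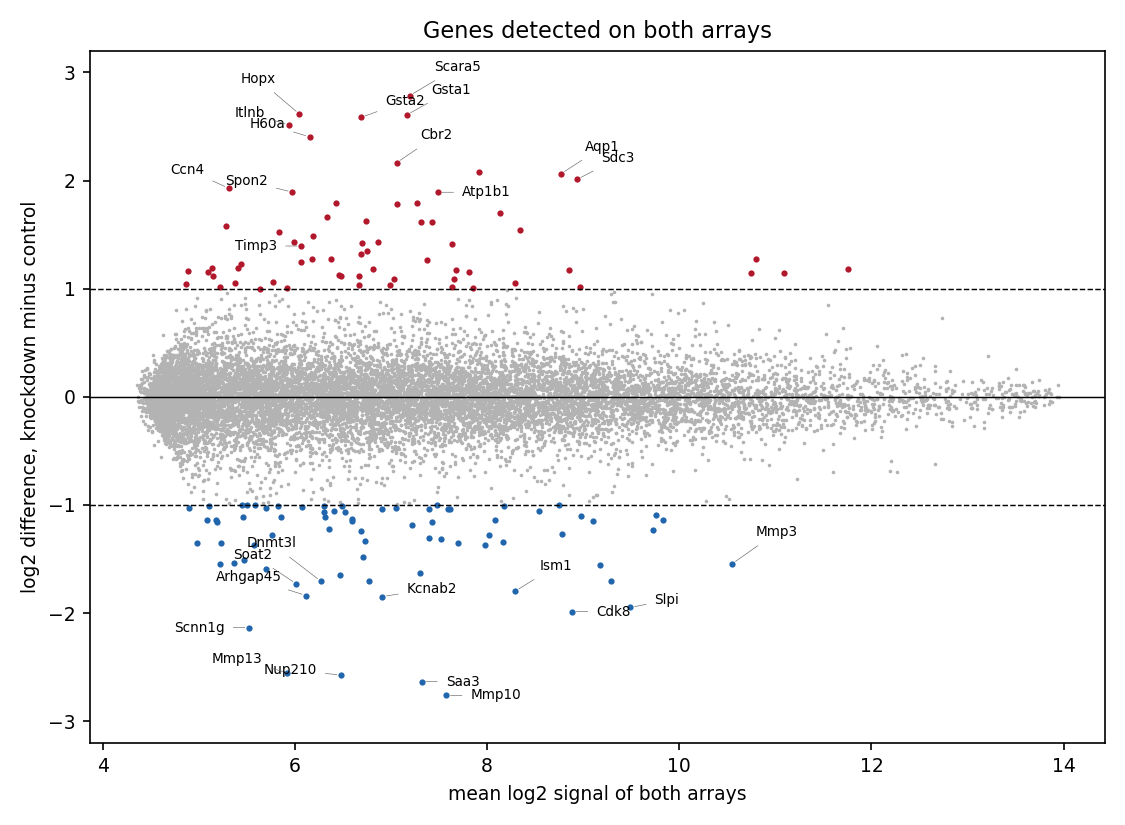
Each point is 1 of the 13613 genes detected on both arrays, with its mean log2 signal on the x axis and the log2 difference, knockdown minus control, on the y axis. Red and blue points are the 67 genes at least 2-fold higher and the 75 at least 2-fold lower, dashed lines mark 2-fold, and the most different symbols, Mmp3 and Timp3 are labelled. By the mean over probes, Mmp10 is the lowest of the labelled genes at -2.76 and Scara5 the highest at 2.79. The brightest probes of Mmp13 and Ccn4 differed more, by -5.23 and 3.23.

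Of the metalloproteinase genes, 3 were at least 2-fold lower in the knockdown, and Mmp10 and Mmp13 were among the 12 lowest genes. Mmp10 (stromelysin-2) was 6.78-fold lower, with log2 values of 8.96 and 6.20. By the mean over probes this was the lowest difference among genes with a symbol detected on both arrays. Mmp3 (stromelysin-1) was 2.92-fold lower, from 11.32 to 9.78, and its 3 probes gave differences from -1.61 to -1.46. Mmp13 (collagenase-3) was 5.86-fold lower as a mean of 3 probes that disagreed in size. Its brightest probe differed by -5.23, below Mmp10. The next was at least 4.32-fold lower because the knockdown array did not detect it, and a probe close to background on both arrays differed by -0.03. No other metalloproteinase gene reached 2-fold. Of 23 such genes on the array, 11 were detected, 4 of them lower and 3 higher by more than the SD between probes of 0.21. Mmp9 (gelatinase B) had a difference of -0.23 and Mmp2 (gelatinase A) of 0.05. Mmp11 and Mmp28 differed by 0.07 and 0.29, and Mmp19, detected in the knockdown only, was at least 1.15-fold higher. Mmp14, a membrane-type enzyme, had a mean of 0.22, with 0.63 at its bright probe, while a dim one, detected in the control only, was at least 1.05-fold lower. It lies on chromosome 14, whose genes had a median of 0.20. Its mean is close to that shift only with the dim probe averaged in. The bright probe lay above the median of 0.28 of the chromosome's bright genes. Mmp1a and Mmp24 differed by 0.01 and -0.06, and their sign changed with the processing. The list's median was 0.01, at percentile 55.5 of random lists, so the large differences belonged to 3 genes and not to the family.

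Among inhibitors of these proteases, Timp3 was 2.63-fold higher in the knockdown as a mean of 3 probes. The probes detected on both arrays differed by 1.65 and 1.96, and the dimmest, detected in the knockdown only, was at least 1.19-fold higher. Reck, a membrane-anchored inhibitor, differed by 0.44. The abundant inhibitors Timp1 and Timp2 differed by -0.08 and -0.10. The inhibitor list had a median of 0.18 over 4 detected genes, at percentile 95.4. In the plasminogen system, which activates metalloproteinases outside the cell, the urokinase gene Plau differed by -0.04 with a sign that changed with the processing, its receptor gene Plaur by -0.11, and Plat by 0.26. Plg was near background and, detected in the control only, at least 1.15-fold lower. The median of the 4 genes was -0.07, at percentile 29.1. The related ADAM and ADAMTS proteases had a median of 0.03 over 14 detected genes, at percentile 60.2. Within that list, Adam33 differed by 0.77 and Adam8 by 0.61, or 0.47 at its probe detected on both arrays. Adamts1, detected in the control only, was at least 1.18-fold lower, and Adam12, detected in the knockdown only, at least 1.94-fold higher.

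**Figure D2:**
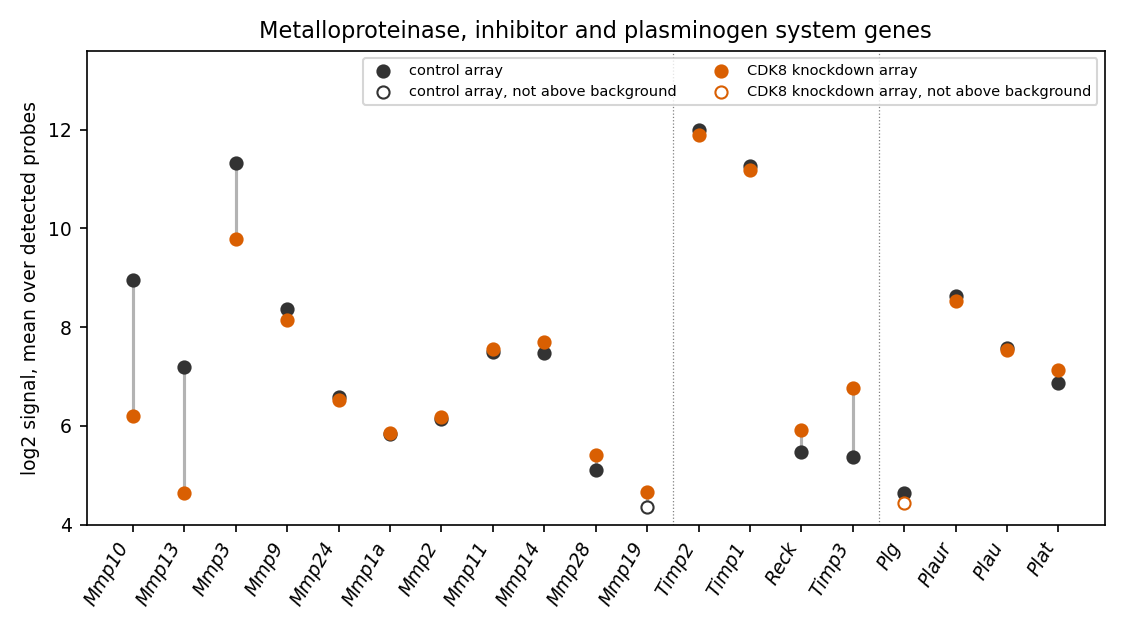
Log2 signal, as the mean over detected probes, of the metalloproteinase, inhibitor and plasminogen system genes (left, middle and right) on the control array (dark) and the knockdown array (orange). Open circles mark an array on which the gene was not above background, and each group of the design has 1 array. Mmp10, Mmp13 and Mmp3 were lower in the knockdown by 6.78-, 5.86- and 2.92-fold, and Timp3 was 2.63-fold higher; signals of different genes are not comparable.

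The other members of the Mediator kinase module were not lower along with Cdk8. Its paralog Cdk19 differed by 0.38, Med12 by 0.36, Med13 by 0.61 and Med13l by 0.29. The Med13 value came from 1 of its 3 probes, close to background on the control array (raw intensity 95.8), and was as low as 0.20 under alternatives. Ccnc, the cyclin partner, differed by -0.04, with a sign that changed with the processing. The module's median was 0.33 over 6 detected genes, at percentile 99.8, but 0.15 at percentile 88.6 when only bright probes were kept, a limit chosen after seeing the data. The core Mediator subunits had a median of -0.07 over 26 genes, at percentile 9.94. Med30 stood apart from them with a difference of -1.14 (log2 10.40 and 9.26, 1 probe). Med10 differed by -0.46, Med4 by 0.34 and Med16 by 0.27.

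By the mean over probes, the highest genes in the knockdown were Scara5, a ferritin-binding scavenger receptor, at 6.90-fold, and Hopx, a homeodomain-only protein, at 6.12-fold. The glutathione transferase genes Gsta1 and Gsta2 differed by 2.61 and 2.58, or about 6-fold. They are close paralogs whose probes can read each other's transcripts, so their values are not certain to be separate observations. Itlnb (5.71-fold) and H60a, a ligand of an activating natural killer cell receptor (5.29-fold), followed. On the control array Hopx, Itlnb and H60a were close to background (raw intensities 99.2, 98.2 and 103.3), so the sizes of their differences are uncertain. Under alternatives their log2 differences were as low as 1.33, 1.60 and 1.61. The Hopx value came from 1 of its 2 probes, and the other was at background on both arrays. Cbr2 was 4.48-fold, the water channel Aqp1 4.17-fold and the syndecan Sdc3 4.03-fold higher. Ccn4 was 3.81-fold higher as a mean over a probe at 3.23 and a dim probe that was at least 1.24-fold higher because the control array did not detect it. The probe at 3.23 lay above Scara5 at 2.79, but its control value was close to background. Spon2 and the sodium pump subunit Atp1b1 were both 3.71-fold higher. Spon2 was likewise close to background on the control array (raw intensity 105), and its log2 difference was as low as 1.22 under alternatives. Among genes detected in the knockdown only, the largest bounds were at least 2.48-fold for Srpx2, 2.15-fold for Prss22, 1.94-fold for Adam12, 1.88-fold for Slc22a18 and 1.76-fold for Pheta2.

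Besides the metalloproteinases, the lowest genes in the knockdown were Saa3, an acute-phase serum amyloid, at 6.20-fold lower, and the nuclear pore gene Nup210 at 5.95-fold lower. The epithelial sodium channel subunit Scnn1g was 4.39-fold lower and the secreted protease inhibitor Slpi 3.86-fold lower. Scnn1g was close to background on the knockdown array (raw intensity 94), so its size is uncertain. Under alternatives the log2 difference of Scnn1g was as small as -1.22. Kcnab2 was 3.60-fold, Arhgap45 3.58-fold and Ism1 3.47-fold lower. Soat2, a cholesterol-esterifying enzyme, was 3.32-fold lower, and Dnmt3l, a DNA methyltransferase cofactor, 3.26-fold lower. Of genes detected in the control only, Akr1c18 was at least 6.48-fold lower, Magee1 at least 6.23-fold, Gpr23 at least 4.80-fold, Fam110c at least 4.13-fold and the calprotectin subunit S100a8 at least 3.84-fold. Of the 24 genes at the ends of the ranking, all 24 kept their direction and a 2-fold size under each of the other normalizations.

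Genes of sterol and fatty acid synthesis were lower as a group. The median of 28 detected genes was -0.34, below all 10000 random lists. Of these, 17 were lower by more than the SD between probes and 1 was higher, the regulator Srebf1 at 0.42. Mvk, a mevalonate pathway kinase, differed by -0.81 and Insig1 by -0.72. No gene of the list reached 2-fold. Among 20 sterol enzymes and regulators, a subset chosen after seeing the data that leaves out Srebf1, 19 were below 0 and the median was -0.41.

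Inflammatory and immediate early genes were also lower as groups. The NF-kB target list had a median of -0.23 over 28 genes, below all 10000 random lists, with 15 genes lower and 4 higher by more than the SD between probes. Saa3, the chemokine genes Ccl2 (-0.96) and Cxcl10 (-0.94) and the apoptosis inhibitor Birc3 (-0.66) were the members with the largest differences. Nfkb2 (0.48) and Traf1 (0.50) lay on the other side. The immediate early list had a median of -0.14 over 23 genes, at percentile 1.25. Fos and Klf2 both differed by -1.01, Dusp6 by -0.93 and Egr1 by -0.92, while Klf4 differed by 0.79 and Jun by 0.61. Interferon-stimulated genes had a median of -0.07 over 41 genes, at percentile 5.8, and below 2.5 under 6 of 15 alternatives. In that list Ifi27l2a was 2.94-fold and Oasl1 2.01-fold lower, and Rsad2 differed by -0.95. The MHC class I presentation list, which shares 3 genes with it, lay on the other side, with a median of 0.21 over 16 genes at percentile 99.98 and 15 genes above 0. Its largest differences were in the immunoproteasome subunits Psmb8 (0.69) and Psmb9 (0.64), the peptide transporter Tap1 (0.57) and Psme1 (0.38).

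Extracellular matrix genes and TGF-beta target genes were higher as groups, and so were the markers of fibroblasts. The matrix list had a median of 0.27 over 39 genes, above all 10000 random lists, with 21 genes higher and 8 lower by more than the SD between probes. Col1a1 was 2.66-fold and Col6a3 2.42-fold higher, Col4a5 differed by 0.89, and Lum was at least 1.71-fold higher because the control array did not detect it. The TGF-beta list had a median of 0.25 over 23 genes, also above all 10000 random lists. Acta2, smooth muscle actin, was 3.08-fold higher, with its probes between 1.32 and 1.86, and Col1a2 differed by 0.84, while Ccn2, a direct target of the pathway, was 2.13-fold lower. Without the genes shared with the matrix list the median of 19 TGF-beta targets was 0.21. The fibroblast markers had a median of 0.52 over 10 detected genes, above all 10000 random lists, and share Col1a1, Col1a2, Col3a1, Dcn, Lum and Postn with the matrix list; Pdgfrb (-1.0) and Col3a1 (-0.60) were lower. The mesenchymal list had a median of -0.05 at percentile 26.0, with Fn1 at 0.70, Snai1 at 0.59 and, besides Pdgfrb, Snai2 at -0.49; with bright probes only, a limit chosen after seeing the data, the median was 0.14 at percentile 98.4. Integrin and adhesion genes had a median of 0.00 at percentile 54.4, with differences of 0.46 for Itga6, 0.43 for Alcam and 0.42 for Itgb7, and with Itga2, detected in the knockdown only, at least 1.28-fold higher; the lowest was Icam1 at -0.36.

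The Wnt and beta-catenin target list had a median of -0.16 over 17 genes at percentile 1.84, and it stayed below the central 95% under 7 of 15 alternatives. With a 5% detection limit the median was -0.02, at percentile 35.4. It was 0.05 with bright probes only, 0.02 with probes whose gene number was in the gene table and -0.05 without the genes of chromosome 14, all chosen after seeing the data. Apcdd1 was 2.42-fold lower, Axin2 differed by -0.49 and Bmp4 by -0.41, while Ccn4 was higher. Epithelial genes had a median of -0.19 over 12 genes at percentile 2.09. Many of them lay near background, and the 9 detected on both arrays had a median of -0.14 at percentile 5.5. Krt20 was at -0.94, the intestinal transcription factor Cdx2 at -0.93 and Elf3 at 0.80 (0.41 at its probe detected on both arrays). Ocln, detected in the control only, was at least 1.14-fold lower. The heat shock list, fixed in advance as 1 of 4 control lists, had a median of -0.15 over 12 genes at percentile 0.85, with Hspb1 at -1.01. The epithelial list stayed below the central 95% under only 7 of 14 alternatives and the heat shock list under 10 of 15. Their percentiles rose to at most 10.2 for the epithelial and 34.3 for the heat shock list.

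S phase genes had a median of 0.03 over 37 genes at percentile 83.2, and mitotic genes of 0.00 over 35 genes at percentile 51.8. The largest differences were in Prim1 (-0.55), Cdc6 (-0.48) and Gins1 (0.37) for the first and in Pttg1 (-0.50) and Prc1 (0.38) for the second. Ribosomal protein genes had a median of -0.02 at percentile 47.0, housekeeping genes of 0.00 at percentile 58.1 and oxidative phosphorylation genes of -0.06 at percentile 7.3, with 35 of 45 genes below 0. As these and the heat shock genes served as control lists, percentiles near either end of the scale need not reflect CDK8. Hypoxia targets had a median of 0.06 at percentile 83.8, with Car12 at 0.71, Pdk1 at 0.53 and Ndrg1 at -0.40, while Egln3 had a mean of -0.46 and -1.04 at its brightest probe. Glycolysis genes had a median of 0.07 at percentile 92.7, although the phosphofructokinase gene Pfkp was 2.40-fold higher and Pfkl differed by 0.56; Slc16a3, near background, differed by -0.39 at its probe detected on both arrays. Targets of p53 had a median of 0.09 at percentile 96.2, with Sesn1 at 0.55, Ephx1 at 0.49, Cdkn1a at 0.31 and Trp53inp1 at -0.42, and with 6 genes higher and 5 lower by more than the SD between probes. The unfolded protein and ATF4 list had a median of -0.06 at percentile 13.0, with Vldlr at 0.95 and Ddit3 at -0.57. The NRF2 and oxidative stress list had a median of -0.04 at percentile 28.0, even though Gsta1, Gsta2 and Gsta4 (3.25-fold) were higher, and Nqo1, a standard target, differed by -0.85.

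**Figure D3:**
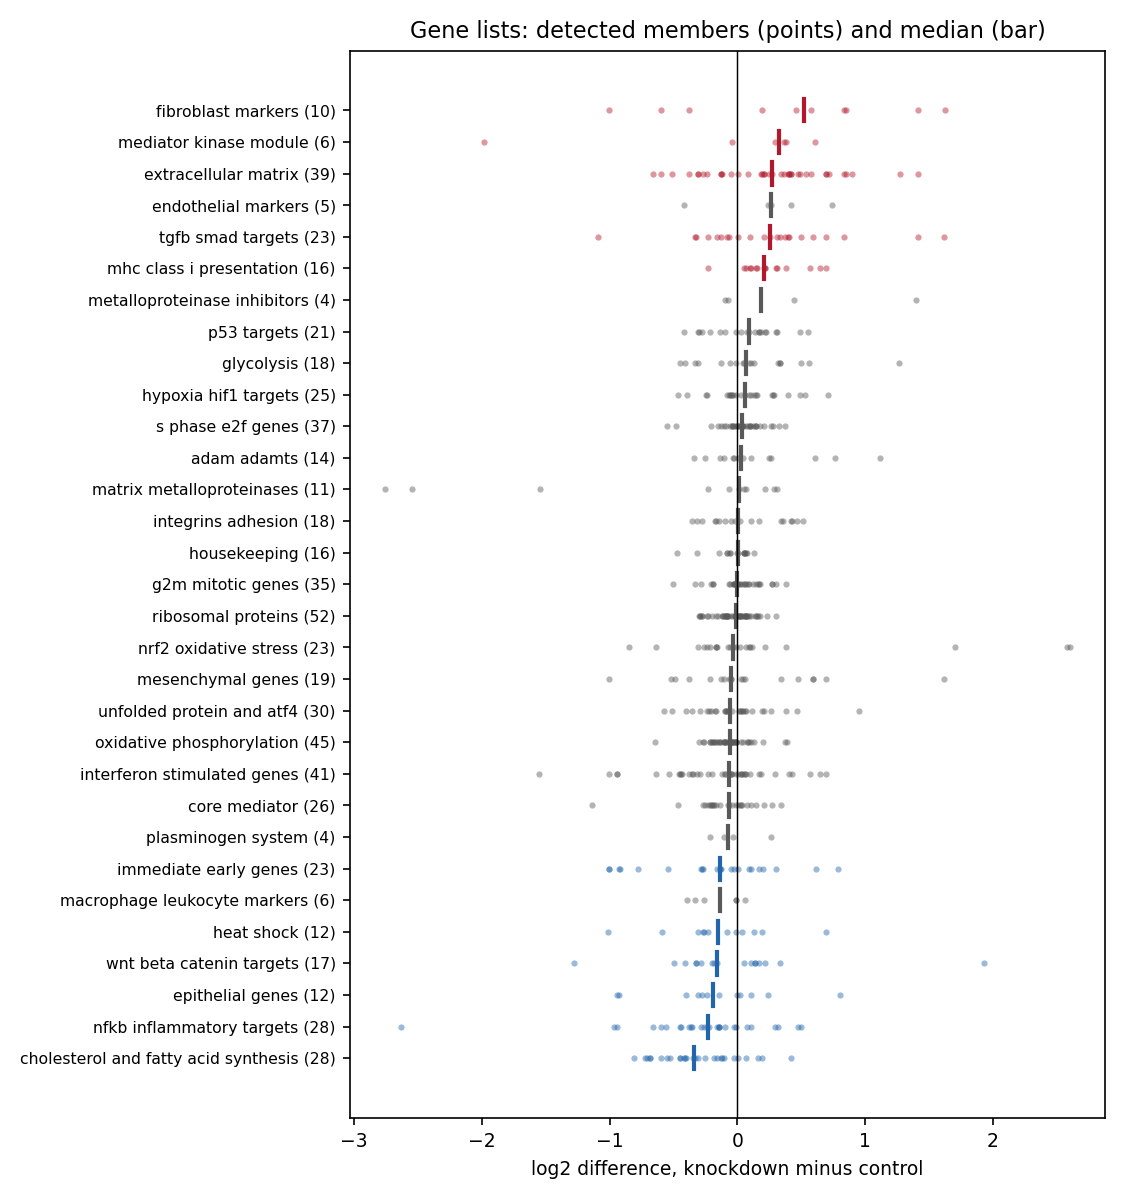
Log2 differences, knockdown minus control, of the detected genes of each list (points; number of genes in brackets) and the list median (bar), with 1 array per group. Red and blue mark the 5 lists above and the 6 lists below the central 95% of matched random lists. The sterol and fatty acid synthesis list has the lowest median at -0.34 and the fibroblast markers the highest at 0.52.

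Of the 31 lists with a percentile, 11 lay outside the central 95% of random lists. Markers of other cell types besides fibroblasts were few. Leukocyte markers had a median of -0.14 over 6 detected genes at percentile 10.5, and endothelial markers of 0.26 over 5 genes at percentile 97.4. Of 10 hepatocyte markers, 2 were detected, Apoa1 at -0.20 and Serpina1a, in the knockdown only, at least 1.43-fold higher. Genes of chromosome 14, grouped with the gene table of assembly GRCm38.p6 and looked at only after the data were seen, had a median of 0.20 over 411 genes, a 1.15-fold difference, and 76.4% of them were higher in the knockdown. The medians of the other chromosomes lay between -0.07 and 0.07. Of the 2-fold genes, 4 higher and 2 lower ones lie on chromosome 14. Of the genes named above, Scara5, Mmp14, Plau, Med4, Bmp4 and Psme1 lie there.

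**Figure D4:**
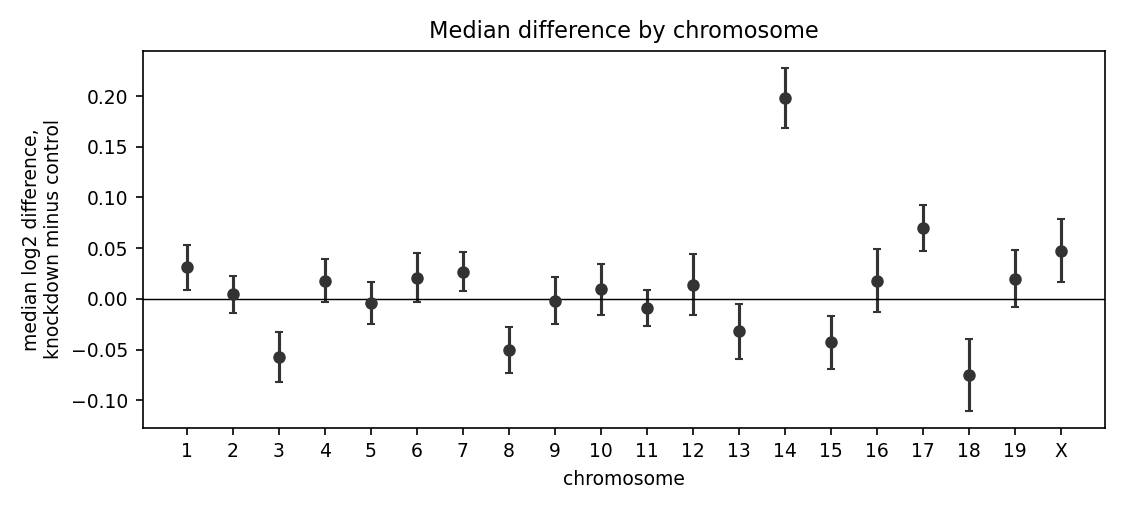
Median log2 difference, knockdown minus control, of the detected genes of each chromosome (points), with bars of 2 SD of the medians of random gene lists of the same size matched on mean expression, 1 array per group. Chromosome 14 lies at 0.20, and the other chromosomes between -0.07 and 0.07.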

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

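The settings for bright probes, probes with a known gene number, another normexp fit, scaling on detected probes and leaving out chromosome 14 were chosen after seeing the data; the others were fixed before. The number of 2-fold genes depended on how dim signals were treated. With an offset of 50, 33 genes were higher and 34 lower, in place of 67 and 75, which follows from the construction, since a larger offset shrinks differences of dim genes. With only probes over 20 background SD, 39 were higher and 44 lower, fewer genes being tested. Without background correction 48 genes were lower. That setting subtracted only the lowest value of each array, so the background left in acts as a larger offset and also shrinks differences of dim genes. How far this accounts for the count was not tested. From the authors' processed values 49 genes were lower, and the cause was not tested. Under the remaining settings both counts stayed within 1.5 times of the main ones. Cdk8 differed by -0.69 without a detection limit, because that average takes in 2 probes at background, and under the other settings it stayed between -1.99 and -1.84. Of 1620 values of 128 named genes under alternatives, 155 moved by more than the SD between probes, and for the genes at 2-fold or more 0 changed sign; Ccnc, Mmp1a, Mmp24 and Plau, all near 0, did. Of 463 list medians under alternatives, 59 moved by more than the SD of random lists, and 2 changed sign among the lists outside the central 95%: the Wnt list was 0.052 with bright probes and 0.020 with probes that have a known gene number; the cause was not tested. The sterol, NF-kB, immediate early, matrix, TGF-beta, MHC class I and fibroblast lists stayed outside the central 95% on the same side under all 15 alternatives, but the sizes of several medians did not hold. The fibroblast median lay between 0.19 and 0.79, the TGF-beta median between 0.10 and 0.32, the matrix median between 0.20 and 0.44, the NF-kB median between -0.29 and -0.13 and the immediate early median between -0.24 and -0.07. The epithelial and heat shock medians rose to at most -0.04 and -0.03. Of the lists inside the central 95% in the main setting, the mesenchymal list turned sign and lay above it with bright probes, at 0.14, and the interferon list lay below it under 6 alternatives, the p53, endothelial and oxidative phosphorylation lists outside under 3 each and the inhibitor, glycolysis and leukocyte lists under 1 each. With genes of 1 array set at their bounds, the Wnt median was -0.06, the NF-kB median -0.15, the matrix median 0.21, the TGF-beta median 0.21, the epithelial median -0.16 and the hypoxia median 0.01. Signal over background limits dim genes most, and no replicate limits every statement. No paired analysis was possible because each group has 1 array.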

Other observations

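The tests of chromosome 14 by random lists, by blocks, by brightness and by copy number, the cell cycle and fibroblast tests and the scan of gene families were chosen only after the results were seen; the tests of the sterol and matrix lists by normalization and by chromosome were set before theirs. Grouping detected genes by the start of their symbol gave 132 families of at least 10 genes, a size raised from 6 (301 families, 25 of them outside the central 95% of matched random lists) after a first scan. Of the 132, 12 lay outside, where 6.6 would be expected if the genes of a family varied independently. They need not do so, and no culture was repeated, so these counts cannot show an excess over chance. The annexins, calcium-dependent membrane-binding proteins, had a median of 0.35 over 11 genes, with 8 above 0, and the collagens of 0.20 over 26 genes. The keratins had a median of -0.25 over 17 genes, with 12 below 0, and the mitochondrial ribosomal proteins of the large subunit of -0.11 over 45 genes, with 32 below 0.

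The 3 strongly lower metalloproteinase genes belong to a run of 10 neighbouring metalloproteinase genes in assembly GRCm38.p6. Of this run, 4 were detected: Mmp13 (-2.55), Mmp3 (-1.54), Mmp10 (-2.76) and, between Mmp3 and Mmp10, Mmp1a (0.01). The lower values were thus not seen in every detected gene of the run, but this rests on Mmp1a alone, read by 1 dim probe of its 3. Mmp12, Mmp1b, Mmp8, Mmp27, Mmp20 and Mmp7 were not above background on either array.

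Genes of chromosome 14 had a median of 0.20, and 10000 of 10000 matched random lists lay lower, which argues against chance; yet 10 of the 20 chromosomes lay outside the central 95%, so single chromosomes differ more than random lists do. A single region does not account for it, since 6 of 6 consecutive blocks of its genes lay above the central 95% of random lists, with medians from 0.13 to 0.29. A bias of normalization with brightness was to be kept if the median fell under 0.10 in any of 7 normalizations or 3 brightness groups, and the dim group, at 0.034, met that bound; the groups were then separated after this was seen, because a uniform shift as large as that of the bright group (0.28) would leave only 0.08 in dim genes after the offset, with an SD of 0.04 over random lists. The lowest value over the normalizations and the middle and bright groups was 0.14, which argues against this bias there. The random lists were matched on mean expression, so a bias with brightness common to all chromosomes would have moved them too. As 10000 of 10000 lay lower, this argues against such a bias for the genes of chromosome 14 as a whole. In the dim group alone, at 0.034 with an SD of 0.04, no shift and a uniform shift cannot be told apart. A different number of copies of chromosome 14 in the cultures is a candidate explanation, with 76.4% of its genes higher, but it was found on the same data, no DNA was measured here, and with 1 array per group it may belong to either line and have nothing to do with CDK8.

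Sterol and fatty acid synthesis genes had a median of -0.34. The normalization is an unlikely source, because the median nearest to 0 over 7 other normalizations was -0.25. Of the cell cycle lists the lower lay at percentile 51.8. This does not decide on slower growth of the knockdown cells, because such lists do not measure growth rate and the bound was set after the result. None of the list's detected genes lie on chromosome 14, and the medians of the other chromosomes lay between -0.07 and 0.07. Subtracting each chromosome's median left -0.32. This could have moved the list's median only slightly, so it was no test, but shifts that small do not produce a median of -0.34. That CDK8 loss lowers these genes stays a hypothesis: cell density, medium, effects of the hairpin on other transcripts and chance differences between 2 cultures were not tested, and none can be separated from the knockdown with 1 array per group.

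Extracellular matrix genes had a median of 0.27 in the knockdown, with the fibroblast markers higher too. Of 8 fibroblast markers detected on both arrays, 6 were higher. The other 2, Pdgfrb and Col3a1, were lower by more than 2 SD between probes, but that SD is technical. Both are dim, and on the control array so were some of the higher markers, such as Dpt (1.63) and Col1a2 (0.84). Fibroblasts in the knockdown culture therefore cannot be told apart from a change in the tumour cells. The lowest median over 7 other normalizations was 0.20, so the normalization does not account for the pattern. None of the list's detected genes lie on chromosome 14, and the medians of the other chromosomes lay between -0.07 and 0.07. Subtracting each chromosome's median left 0.26. This could have moved the list's median only slightly, so it was no test, but shifts that small do not produce a median of 0.27. A change in the tumour cells may come from CDK8 loss or from a drift between the lines, and these arrays do not separate them.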
